A study of Mus musculus with 6 samples.

How the data were processed

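RNA of mouse stromal vascular fraction cells from inguinal fat, induced to form adipocytes in culture for 4 days, was measured in 3 Ythdf1 knockout and 3 wild-type libraries. Per the labels' protocols, ribosomal RNA was depleted from total RNA and the libraries were read as pairs of 150 bp on an Illumina NovaSeq 6000. The deposited table holds raw counts per Ensembl gene, whole numbers that were not normalized, for 53801 genes. Per the submitters' processing notes, STAR and featureCounts were used with the mouse builds mm10 and GRCm38, whose coordinates are the same assembly. Their versions, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of genes with near-identical copies, close paralogs or overlapping and antisense neighbours are therefore uncertain, because such reads can be assigned to either or discarded.

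Library columns were matched to samples by the names in the labels, and groups and replicate numbers were taken from the sample titles. Gene symbols, biotypes and coordinates came from GENCODE mouse release 21 on GRCm38, which held 53706 of the 53801 identifiers, and the other 95 took at most 0.00683% of the counts of a library. Total counts were 18065683, 17693082 and 20089138 in knockout replicates 1 to 3 and 17566436, 16619605 and 17700068 in wild-type replicates 1 to 3. A floor of 3 counts corresponded to 0.149 to 0.181 CPM, and such floors cover counting error only. Replicates of a genotype were distinct libraries, since the chi-square of their counts per degree of freedom was between 9.30 and 23.9, against 143 to 216 between genotypes. Ribosomal RNA took 0.143% of counts in wild-type replicate 2 and 0.0203% to 0.0273% in the other libraries.

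Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 14816 of the 28268 genes with any count. Libraries were scaled with TMM, whose factors lay between 0.975 and 1.02, and CPM values are relative to these scaled totals of the genes kept. Dispersions were estimated robustly (common biological coefficient of variation 0.123), and genotypes were compared with the legacy robust quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment at 0.05 and genotype as the single term. Log2 fold changes are knockout over wild type and are given with standard errors where printed as ±. The series states that replicates are biological, so p-values refer to the spread between such replicates. They do not cover a difference in isolation, culture or library preparation that coincided with genotype.

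Before the data were examined, 38 gene lists were fixed from general knowledge. The 34 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation (median 0.187) and with fry from limma 3.58.1. Counts of changed members are given over all genes tested and adjusted over the list alone. The genes named were also set by a rule made beforehand. It took Ythdf1, then the 12 largest rises and 12 largest falls among genes past the threshold with separated genotypes, a mean of at least 5 CPM in the higher genotype and no predicted-model symbol, then up to 4 members of each list with the smallest p, or the 2 most abundant where none passed, and a short set of adipocyte and m6A genes. Other members of the fixed lists, among them Scd1, Fasn, Plin1, Slc2a4, Pnpla2, Lipe, Elovl3, Pcx, Col1a1, Col3a1, Col5a3, Col6a3, Col15a1, Ccn2, Pdgfra, Ly6a, Mki67, Adgre1, C1qa, Mpeg1 and Ptprc, and members of counts of 6 or fewer, were named after their values had been seen. So were the pseudogene copies and the genes of other organs.

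The fit was tested on simulated counts for the 14816 genes with the means and library sizes of these samples, in which 50 genes were changed at each of 4 fold sizes. It gave 9 false calls, and 0 of 40 random lists passed camera. Genes were simulated independently of each other, so this does not test camera on lists whose members vary together. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, edgeR without the legacy setting, no low-count filter, a filter of 1 CPM in 3 samples, the replicate number as a block, the L0 or L1 suffix of the library names as a covariate, protein-coding genes alone, no mitochondrially encoded genes, a log2 fold change of at least 1, and each replicate left out. Removal of the 50 most abundant genes and offsets for GC content and transcript length, available for 99.9% of the tested genes, were added after the data had been seen. What the library suffix stands for is not stated in the labels; L0 occurs once in each genotype. Processed pseudogenes were matched to parent genes with BLAST+ 2.17.0 at 90% identity or more over at least 50% of the copy. Lists of epithelial, liver and other organ genes were written after the falls of gut genes had been seen and before those lists were tested. Their genes were compared only if they had at least 10 counts in total over the libraries. No sample was left out. Values of a few single genes that the naming rule took are not reported here.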

Results

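The study measured the RNA of cultured mouse fat cells labelled wild type or knockout for Ythdf1, which encodes a cytoplasmic protein that binds RNA carrying the m6A methyl mark. Stromal vascular fraction cells, the non-adipocyte cells of fat tissue among which adipocyte progenitors are found, were taken from the inguinal fat of mice that the labels call wild type or Ythdf1 knockout. They were sequenced on day 4 of adipogenic induction in culture. Each genotype had 3 libraries, which the series calls biological replicates. Total counts per library ran from 16619605 in wild-type replicate 2 to 20089138 in knockout replicate 3, so that 3 counts corresponded to between 0.149 and 0.181 CPM. Values are CPM, that is, counts scaled by library size, as mean ± SD with n = 3 per genotype unless stated otherwise.

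The single comparison of the design asked how the transcripts of these cultures differed between Ythdf1 knockout and wild type. Genes of mature adipocytes, of lipid synthesis and breakdown and of mitochondrial respiration were higher in the knockout, and genes of fibroblast-like progenitors, myofibroblasts, collagens, cell division and ribosomal proteins were lower. The adipocyte regulator Pparg was 131 ± 14.4 CPM in knockout and 29.8 ± 5.50 CPM in wild type, and the secreted adipocyte hormone Adipoq was 942 ± 78.4 against 185 ± 55.6 CPM. The smooth muscle actin gene Acta2 was 90.1 ± 12.9 CPM in knockout and 741 ± 149 CPM in wild type, and the fibrillar collagen gene Col1a1 was 7480 ± 385 against 17724 ± 1055 CPM. Markers of macrophages were also higher in the knockout, most of all in replicate 3, where Adgre1 was at 79.4 CPM against 33.4 and 29.9 CPM in replicates 1 and 2. These gene groups passed camera with a preset correlation, and none did with an estimated correlation, where their adjusted p-values ran from 0.0824 to 0.601.

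The targeted gene, Ythdf1 (ENSMUSG00000038848), lies on the minus strand of chromosome 2 between 180904377 and 180920949 in GRCm38. Its raw counts were 820, 754 and 892 in the knockout libraries and 1114, 1005 and 1056 in the wild-type libraries. The level was 43.8 ± 1.15 CPM in knockout and 61.8 ± 1.34 CPM in wild type, a log2 fold change of -0.50 ± 0.08 (SE) with an adjusted p of 0.000378 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fold was 0.709, with a 95% interval from 0.629 to 0.799. All 3 knockout values lay below the wild-type values, but most of the transcript signal remained. The labels do not say which part of the gene was removed and the counts are for the whole gene, so this value checks the labels only in part.

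Most other genes of the m6A machinery, 15 of 23, did not pass the test. Of all 14816 genes tested 44.3% passed, so most genes of any kind did not either. The readers Ythdf2 and Ythdf3 were at 41.9 ± 1.16 against 37.0 ± 2.86 CPM and 113 ± 6.01 against 110 ± 3.94 CPM in knockout and wild type, with edgeR adjusted p-values of 0.13 and 0.71. The methyltransferase genes Mettl3 and Mettl14 had log2 fold changes of 0.07 and 0.04, and the demethylase gene Fto had -0.07, with edgeR adjusted p-values of 0.71, 0.84 and 0.51. Among the 23 writers, erasers and readers tested, Zcchc4 and the demethylase gene Alkbh5 rose, by 0.43 and 0.31 on the log2 scale, and 6 fell. Those were Igf2bp1 (log2 fold change -2.52), Igf2bp3 (-1.10), Fmr1 (-0.86), Rbm15b (-0.45), Ythdc2 (-0.37) and Virma (-0.25). Adjusted over the list alone, 2 were higher and 5 lower. The call for Alkbh5 (edgeR adjusted p = 0.011) ended without knockout replicate 1 (adjusted p = 0.053) or wild-type replicate 2 (0.051). As a set the list did not stand apart from other genes (camera adjusted p = 0.422), with a median log2 fold change of 0.02, a mean of -0.17 and a test direction of lower.

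Of 14816 genes tested, 6561 (44.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3342 higher and 3219 lower in knockout. A change of at least 2-fold was found for 1326 of the higher and 991 of the lower genes, and of at least 4-fold for 384 and 255. The 3 knockout values lay wholly above or below the 3 wild-type values for 8177 genes (55.2%), where chance gives 10%. With the suffix of the library name, whose meaning the labels do not state, as a covariate the counts were 3353 and 3210. The first principal component of log2 CPM held 80.7% of the variance and separated the genotypes. In simulated data of this depth and spread the test recovered 10% of genes at the smallest fold simulated. It recovered 56% at 1.5-fold, 70% at 2-fold and 92% at 4-fold. Only 50 of 14816 genes were changed at each fold there, against 6561 called here. The adjusted threshold is stricter when fewer genes change, so these shares do not give the recovery in this comparison. A small change in a gene named here as not passing still cannot be excluded.

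Among genes that reached 5 CPM, separated the genotypes and had no predicted-model symbol such as Gm8730, the rises were led by Eno1b, at 126 ± 24.6 CPM in knockout and 1.71 ± 0.289 in wild type (log2 fold change 6.20). Eno1b is, however, 99.45% identical to the glycolytic gene Eno1 over the aligned stretch and its count is uncertain. Next came Ucp1, the uncoupling protein of thermogenic fat, at 6.05 ± 2.86 against 0.154 ± 0.116 CPM (log2 fold change 5.21). Its raw counts were 119, 152 and 61 in knockout and 5, 2 and 1 in wild type. With 1 library left out the log2 fold change of Ucp1 ran from 4.82 to 5.97, the highest without wild-type replicate 1. Cacng6 (4.99), Cfd, the adipocyte-secreted complement factor D or adipsin (4.67), Depp1 (4.49, and 5.30 without wild-type replicate 3), the fatty acid receptor gene Ffar4 (4.29), the lipogenic regulator Thrsp (4.22), the amino acid transporter gene Slc7a10 (4.16), Slc25a34 (4.14), Scd3 (4.09), Acaa1b (4.04) and Reep6 (3.84) completed the 12 largest of these by log2 fold change. Predicted copies of other genes rose by as much or more, Gm7049 by 6.49 (7.59 without wild-type replicate 1) and Gm8730 by 5.84 on the log2 scale, and were left out by that rule. Scd3 and Acaa1b have close paralogs, Scd1 and Acaa1a, with which they can share reads.

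The 12 largest falls under the same rule included Col11a1, a fibrillar collagen gene, at 10.004 ± 1.13 CPM in knockout and 242 ± 29.8 CPM in wild type, a log2 fold change of -4.60. Other falls were the neuropeptide Y receptor gene Npy1r (-4.61), the peptide hormone gene Cck (-4.40), Brinp3 (-5.11), C1qtnf3 (-3.97), Aldh1a2, which makes retinoic acid (-3.91), and Prol1 (-4.50). The call for Prol1 (edgeR adjusted p = 0.018) was the least secure. It ended under DESeq2 (0.063), with the replicate block, without the low-count filter (0.115), and without knockout replicate 2 (0.103) or 3 (0.069). Its raw counts were 14, 0 and 0 in knockout and 50, 188 and 54 in wild type. With 1 library left out its log2 fold change ran from -9.70, without knockout replicate 1 and so against libraries at 0, to -3.52 without wild-type replicate 2, and was -3.86 without knockout replicate 3. The remaining falls were genes of gut lining at low levels, Dmbt1 (0.330 ± 0.289 against 15.5 ± 3.82 CPM, log2 fold change -5.50), Lypd8 (-4.96), Car1 (-4.96), Muc3 (-4.51) and Pigr (-4.04). With 1 library left out the log2 fold change of Car1 ran from -6.35 to -4.43. That of Muc3 ran from -5.23 to -3.94. The lowest values were those without knockout replicate 3 for Car1 and for Lypd8 (-5.58), and without knockout replicate 2 for Muc3 and for Pigr (-4.68). Of 34 other genes of colon epithelium, listed after these falls had been seen, 29 had counts in all 3 wild-type libraries above every knockout library. Their levels were low. Clca1 was at 3.68 ± 0.269 CPM in wild type and 0.251 ± 0.1996 in knockout, and Agr2 at 2.32 ± 0.280 CPM in wild type with 0 counts in each knockout library.

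Mature adipocyte markers rose together. Of 27 tested, 26 were higher and 0 lower, the same counts as adjusted over the list alone, and the median log2 fold change was 2.12. The exception, Nnat, had a log2 fold change of -0.39 and did not pass. The fatty acid carrier gene Fabp4 was at 9178 ± 2053 CPM in knockout and 1846 ± 351 in wild type, the lipid droplet gene Plin1 at 811 ± 15.8 against 174 ± 57.5, the insulin-responsive glucose transporter gene Slc2a4 at 119 ± 24.3 against 10.2 ± 4.11, and the glycerol channel gene Aqp7 at 46.6 ± 3.29 against 8.44 ± 2.03. The camera adjusted p of the list was 1.4e-27 with the preset correlation, and adjusted p = 0.19 with an estimated correlation. The leptin gene Lep, with 2, 5 and 4 counts in knockout and 3, 11 and 4 in wild type, was too low to test.

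Among 22 adipogenic transcription factors, 14 were higher and 3 lower, and adjusted over the list alone 15 and 3 (median log2 fold change 0.44, camera adjusted p = 4.2e-05, and adjusted p = 0.31 with an estimated correlation). Cebpa was at 341 ± 42.9 CPM in knockout and 112 ± 30.0 in wild type, and the lipogenic regulator Srebf1 at 308 ± 9.62 against 103 ± 11.6. The liver X receptor gene Nr1h3 and Stat5a rose by 1.96 and 1.04 on the log2 scale. The factors that fell were Klf5 (-1.02), Klf4 (-0.79) and Cebpd (-0.39), which act early in adipogenesis.

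Genes that build fatty acids and triglycerides rose, 20 of 24 with 1 lower, and the same adjusted over the list alone (median log2 fold change 1.44, camera adjusted p = 1.6e-17, and adjusted p = 0.19 with an estimated correlation). The desaturase gene Scd1 reached 24191 ± 856 CPM in knockout against 2686 ± 895 in wild type, and alone took between 2.37% and 2.50% of all counts in the knockout libraries. The fatty acid synthase gene Fasn was at 3009 ± 141 against 501 ± 174 CPM, Acly at 1448 ± 143 against 332 ± 51.6, and Acacb at 269 ± 26.4 against 35.5 ± 9.52. The member that fell was Mogat2 (-2.82), an enzyme gene of intestinal fat absorption.

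Lipolysis and fatty acid oxidation genes rose as well, 24 of 26 with 1 lower, and adjusted over the list alone 25 and 1 (median log2 fold change 1.80, camera adjusted p = 1.1e-30, and adjusted p = 0.19 with an estimated correlation). The triglyceride lipase gene Pnpla2 was at 1578 ± 194 CPM in knockout and 271 ± 94.2 in wild type, and the hormone-sensitive lipase gene Lipe at 567 ± 38.9 against 103 ± 35.6. Cpt1a, the gene for the liver form of the carnitine transferase, fell by 0.36 on the log2 scale.

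Of 25 thermogenic and beige adipocyte genes, 17 were higher and 1 lower, and adjusted over the list alone 19 and 2 (median log2 fold change 2.23, camera adjusted p = 3.2e-10, and adjusted p = 0.19 with an estimated correlation). The mitochondrial coactivator gene Ppargc1a was at 15.9 ± 1.85 CPM in knockout and 2.03 ± 1.10 in wild type, Fgf21 at 9.66 ± 1.61 against 0.686 ± 0.157, and Elovl3 at 129 ± 24.96 against 16.9 ± 5.76. Cidea, with raw counts of 88, 87 and 25 in knockout and 0, 2 and 4 in wild type, had a log2 fold change of 4.88, which ran from 4.30 to 5.79 with 1 library left out, the highest without wild-type replicate 3. Prdm16, a regulator of brown and beige fat identity, was at 11.3 ± 0.880 against 9.41 ± 1.40 CPM and did not pass (edgeR adjusted p = 0.18), and Bmp8b was too low to test. The gene that fell, Ckmt1 (-4.91), is also made in gut lining and reached 2.33 ± 0.339 CPM in wild type, and its log2 fold change was -6.05 without knockout replicate 3.

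**Figure D1:**
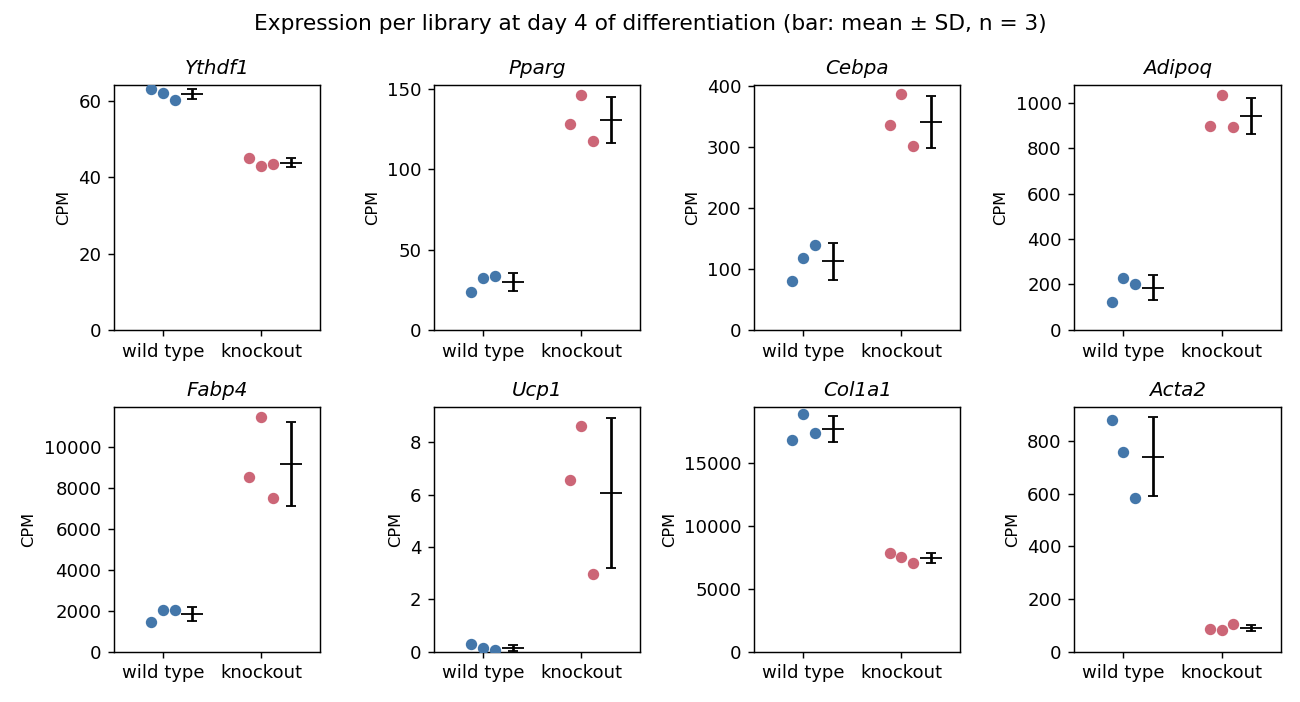
Expression of Ythdf1, Pparg, Cebpa, Adipoq, Fabp4, Ucp1, Col1a1 and Acta2 in CPM (linear vertical axes from 0), with a point for each library and a bar for the mean ± SD of 3 libraries per genotype. The knockout points lie above the wild-type points for Pparg, Cebpa, Adipoq, Fabp4 and Ucp1 and below them for Ythdf1, Col1a1 and Acta2.

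Mitochondrial genes followed the same direction. Of 75 nuclear genes of oxidative phosphorylation, 69 were higher and 0 lower, the same as adjusted over the list alone, with a median log2 fold change of 0.98 (camera adjusted p = 1.0e-23, and adjusted p = 0.345 with an estimated correlation). Cyc1, of complex III, was at 191 ± 34.3 CPM in knockout and 53.0 ± 3.03 in wild type, and Sdha, of complex II, at 549 ± 81.9 against 197 ± 9.14. Each of the 18 genes of the tricarboxylic acid cycle list was higher, over the list alone too (median 1.39, camera adjusted p = 3.4e-22, and adjusted p = 0.229 with an estimated correlation). That list also took in pyruvate carboxylase and pyruvate dehydrogenase genes, which feed the cycle: Pcx, Pdha1, Pdhb and Dlat. The citrate synthase gene Cs was at 855 ± 81.1 against 267 ± 32.6 CPM and the pyruvate carboxylase gene Pcx at 895 ± 121 against 150 ± 40.5. Of 12 transcripts encoded in the mitochondrial genome, 9 were higher and 0 lower, also when adjusted over the list alone (median 0.59, camera adjusted p = 0.0075, and adjusted p = 0.475 with an estimated correlation), with mt-Co1 at 11153 ± 598 against 7286 ± 219 CPM. Mitochondrially encoded RNA took 2.29% to 2.48% of counts in the knockout libraries and 1.53% to 1.602% in the wild-type libraries.

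Glycolysis genes rose, 12 of 18 with 0 lower, the same adjusted over the list alone (median log2 fold change 0.46, camera adjusted p = 0.00023, and adjusted p = 0.415 with an estimated correlation), among them Hk2 (1.15), Pfkfb3 (1.54) and Aldoa (1.06). Cholesterol synthesis and uptake genes were higher for 12 of 24 with 0 lower, and for 13 adjusted over the list alone (median 0.37, camera adjusted p = 0.00021, and adjusted p = 0.345 with an estimated correlation). Insig1 was at 430 ± 44.7 CPM in knockout and 112 ± 21.8 in wild type, and Hmgcs1 at 256 ± 18.4 against 126 ± 13.2. Of 21 insulin signalling genes, 10 were higher and 4 lower, the same adjusted over the list alone (median 0.54, camera adjusted p = 0.0028, and adjusted p = 0.345 with an estimated correlation). The insulin receptor gene Insr rose by 0.99 on the log2 scale, Foxo1 by 1.30 and Pde3b by 2.52, and the falls were Igfbp2 (-1.72), Grb14 (-0.83), Igf1r (-0.65) and Akt1 (-0.41).

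Markers of adipocyte progenitors and fibroblasts fell, 15 of 24 with 0 higher, the same adjusted over the list alone (median log2 fold change -0.78, camera adjusted p = 2.8e-09, and adjusted p = 0.0824 with an estimated correlation). Mfap5 was at 291 ± 11.4 CPM in knockout and 791 ± 40.4 in wild type, Anxa3 at 99.2 ± 3.94 against 251 ± 20.7, and Gdf10 at 17.0 ± 0.424 against 60.3 ± 1.07. The widely used progenitor markers Pdgfra and Ly6a did not pass, at 595 ± 58.1 against 696 ± 44.3 CPM and 1373 ± 71.3 against 1281 ± 82.8 CPM (edgeR adjusted p = 0.11 and 0.45).

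Of 35 extracellular matrix and collagen genes, 22 were lower and 7 higher, and adjusted over the list alone 23 and 8 (median log2 fold change -0.78, camera adjusted p = 1.5e-09, and adjusted p = 0.247 with an estimated correlation). The collagen cross-linking enzyme gene Lox was at 4845 ± 350 CPM in knockout and 16384 ± 310 in wild type, and Postn at 2250 ± 308 against 8499 ± 923. Col1a1 and Col3a1 fell by 1.24 and 1.27 on the log2 scale. Col5a3 moved the other way, at 1328 ± 41.4 against 353 ± 89.9 CPM, as did Col15a1 at 719 ± 38.2 against 328 ± 49.9 and Col6a3 at 2849 ± 182 against 1318 ± 274. Myofibroblast and smooth muscle markers were lower for 13 of 14 with 0 higher (median -1.89, camera adjusted p = 7.2e-15, and adjusted p = 0.19 with an estimated correlation). Adjusted over the list alone, the other member, Smtn, was higher. The growth factor gene Ccn2 was at 49.8 ± 14.8 against 479 ± 147 CPM and Myl9 at 13.5 ± 2.29 against 74.0 ± 16.2.

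Signalling genes of the TGF-beta and BMP families were lower for 17 of 28, with Id2 and Tgfbr2 higher, and adjusted over the list alone the counts were the same (median log2 fold change -0.38, camera adjusted p = 0.00045, and adjusted p = 0.19 with an estimated correlation). Fst was at 41.4 ± 1.97 CPM in knockout and 91.4 ± 3.55 in wild type, and Bmp6 at 2.93 ± 0.316 against 9.49 ± 0.363. Of 27 Wnt signalling genes, 12 were lower and 3, Tcf7l2, Lrp5 and Fzd4, were higher, and adjusted over the list alone 13 and 3 (median -0.39, camera adjusted p = 0.0014, and adjusted p = 0.284 with an estimated correlation). The lower ones included the Wnt inhibitor gene Sfrp1 (872 ± 154 against 2231 ± 132 CPM), Dkk3 (33.5 ± 1.57 against 81.6 ± 0.894) and the receptor gene Fzd2 (35.2 ± 2.09 against 82.8 ± 5.25).

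**Figure D2:**
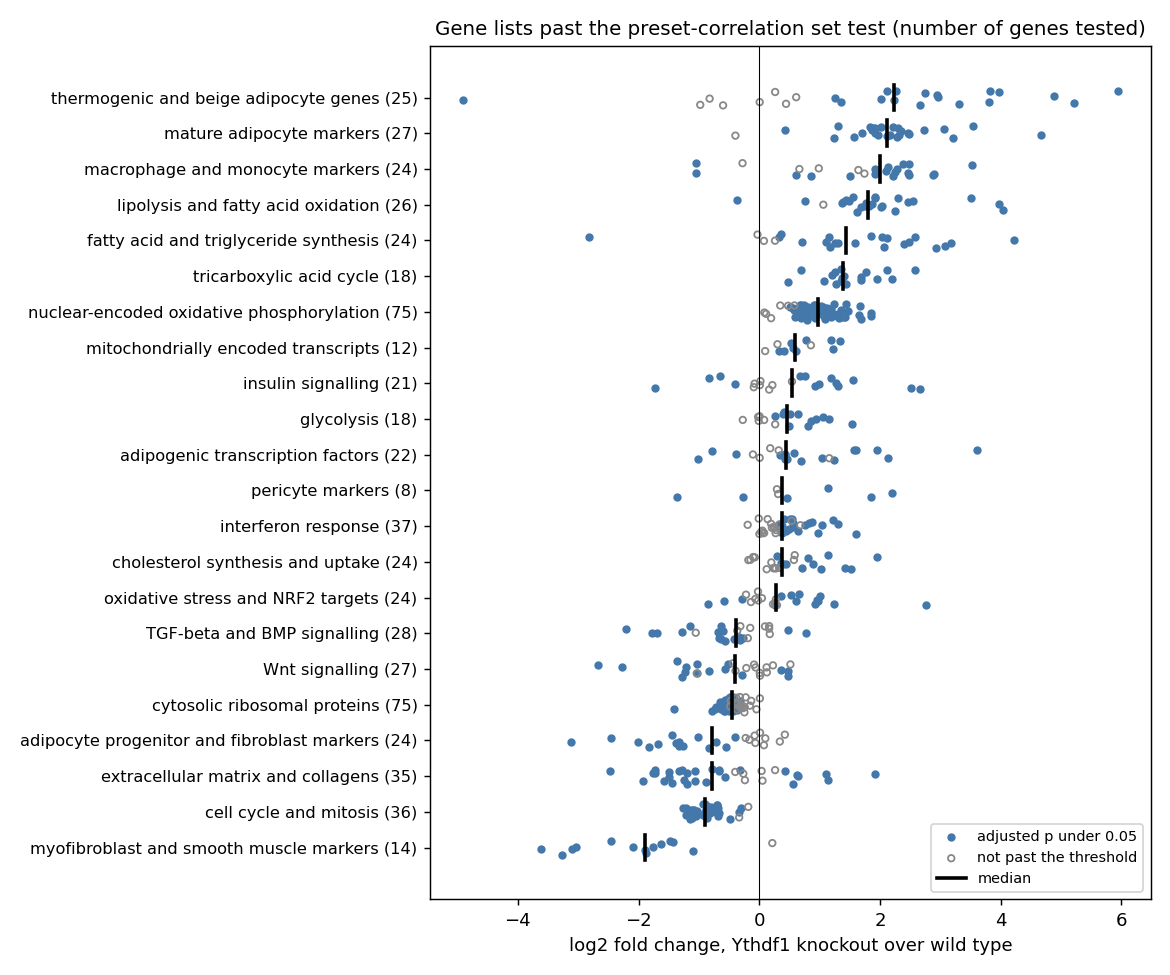
Log2 fold change of knockout over wild type (horizontal axis) for each tested gene of the 22 lists that passed camera with the preset correlation, ordered by median, with filled points for genes past an adjusted p of 0.05, open points for the others and a bar at the median. The medians run from -1.89 for myofibroblast and smooth muscle markers to 2.23 for thermogenic and beige adipocyte genes.

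Cell cycle genes fell, 34 of 36 with 0 higher, the same adjusted over the list alone (median log2 fold change -0.89, camera adjusted p = 1.3e-11, and adjusted p = 0.345 with an estimated correlation). The proliferation marker Mki67 was at 85.7 ± 30.7 CPM in knockout and 184 ± 20.8 in wild type, and the mitotic kinase gene Cdk1 at 23.9 ± 3.62 against 52.0 ± 7.38. Of 75 cytosolic ribosomal protein genes, 56 were lower and 0 higher, and 64 were lower adjusted over the list alone (median -0.46, camera adjusted p = 9.8e-08, and adjusted p = 0.601 with an estimated correlation). Rplp0 had the largest fall, 530 ± 83.6 against 1406 ± 112 CPM, while its near-identical copies Gm8730, Gm9625 and Gm14165 rose, so its level is uncertain. Rps18 fell by 0.79 and Rps26 by 0.59 on the log2 scale. Translation initiation and elongation factors went both ways, 7 higher and 10 lower of 39, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.595), with Eif4a2 rising by 0.61 and Eef1g falling by 0.58 on the log2 scale. Of 21 replication-dependent histone genes listed, only 7 had enough counts to test. None of these passed in edgeR, over the list alone or at an unadjusted p of 0.05 (camera adjusted p = 0.889). The most abundant, Hist1h1c, was at 187 ± 12.8 against 169 ± 16.5 CPM.

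Macrophage and monocyte markers rose, 17 of 24 with 2 lower, and adjusted over the list alone 19 and 2 (median log2 fold change 2.01, camera adjusted p = 0.0017, and adjusted p = 0.601 with an estimated correlation). Adgre1, which encodes F4/80, was at 47.6 ± 27.7 CPM in knockout and 6.37 ± 1.10 in wild type, Mpeg1 at 70.9 ± 36.8 against 15.002 ± 1.40, and C1qa at 17.1 ± 12.1 against 3.51 ± 0.536. The knockout libraries varied widely. The pan-leukocyte gene Ptprc was at 5.06, 4.38 and 12.3 CPM in replicates 1, 2 and 3, and without knockout replicate 3 the median of the list was 1.44. The log2 fold changes of Adgre1, C1qa and Ptprc were 2.90, 2.29 and 2.14 with all libraries and 2.31, 1.53 and 1.51 without that replicate. The members that fell were Spp1 (-1.05), also made by fibroblasts and bone-forming cells, and Cd74 (-1.05). Beside these markers, interferon response genes were higher for 20 of 37 with 0 lower, the same adjusted over the list alone (median 0.37, camera adjusted p = 0.0017, and adjusted p = 0.609 with an estimated correlation). Irf7 was at 513 ± 62.9 against 290 ± 49.9 CPM and Psmb9 at 31.1 ± 3.75 against 13.3 ± 2.07. Inflammatory cytokine and chemokine genes went both ways, 11 higher and 8 lower of 29, also over the list alone (camera adjusted p = 0.947), with a median of 0.03, a mean of -0.19 and a test direction of lower. Il33 was at 66.0 ± 12.7 against 19.1 ± 2.18 CPM, Cxcl14 at 28.5 ± 13.9 against 391 ± 74.2, and Csf1, a macrophage growth factor, at 890 ± 94.4 against 1713 ± 52.0.

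Of 24 oxidative stress and NRF2 target genes, 11 were higher and 3 lower, and adjusted over the list alone 12 and 4 (median log2 fold change 0.27, camera adjusted p = 0.014, and adjusted p = 0.345 with an estimated correlation). Hmox1 was at 739 ± 123 CPM in knockout and 313 ± 21.8 in wild type, and the falls were Nqo1 (-0.85), Gpx1 (-0.58) and Txnrd1 (-0.29). Genes of the unfolded protein and integrated stress response split, 9 higher and 13 lower of 32, and adjusted over the list alone 9 and 14 (median -0.06, camera adjusted p = 0.28). The folding enzyme genes Pdia3 and Pdia6 were at 725 ± 25.4 against 1452 ± 30.8 CPM and 284 ± 16.6 against 556 ± 24.6, while the stress-induced gene Atf3 was at 10.2 ± 1.04 against 2.59 ± 0.261. Of 15 immediate early genes, Atf3, Fosl1 (1.01) and Jun (0.33) were higher and Fosb (-1.43) lower, the same adjusted over the list alone (median 0.05, camera adjusted p = 0.573). The edgeR call for Jun (adjusted p = 0.0048) ended with offsets for GC content and length (adjusted p = 0.051).

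Markers of other cell types that the cultures could hold were mostly few or low, with some exceptions. Among the pericyte markers Steap4 was at 494 ± 16.2 CPM in knockout and 137 ± 36.1 in wild type. Ndufa4l2 was at 337 ± 26.8 against 406 ± 14.7, and Rgs5 only at 0.812 ± 0.441 against 2.14 ± 0.797. Pericyte markers passed as a list of 8, with Cspg4 (2.20), Steap4 (1.85), Mcam (1.15) and Cox4i2 (0.45) higher and Rgs5 (-1.37) and Ndufa4l2 (-0.27) lower, and 5 and 2 adjusted over the list alone (median log2 fold change 0.38, camera adjusted p = 0.0203, and adjusted p = 0.335 with an estimated correlation). That call ended with limma-voom (adjusted p = 0.137), and the edgeR call for Cox4i2 ended without knockout replicate 1 (adjusted p = 0.052), knockout replicate 2 (0.064) or wild-type replicate 1 (0.067). Of 16 endothelial markers, Plvap (1.83), Egfl7 (1.09) and Tek (0.37) were higher and Eng (-0.55) lower, and adjusted over the list alone 2 were higher and 1 lower (median 0.38, camera adjusted p = 0.566). Tek was marginal, with an edgeR adjusted p of 0.034 that rose to between 0.083 and 0.126 without knockout replicate 1 or 2 or wild-type replicate 1 or 2. The call for Tek also ended with the replicate block. Of 7 Schwann cell and neural markers, 5 were higher, among them Cdh19 (3.62, and 4.82 without wild-type replicate 1), Ngfr, Erbb3 and Mbp, and Ncam1 and S100b were lower, also over the list alone (median 0.82, camera adjusted p = 0.976), with Ncam1 at 37.2 ± 6.42 against 175 ± 10.6 CPM. Of 6 chondrogenic and osteogenic markers, Alpl (-2.11), Sp7 (-2.10), Spp1 and Runx2 (-0.30) were lower and 0 higher, also over the list alone (median -0.68, camera adjusted p = 0.0865). That list passed without knockout replicate 3 (camera adjusted p = 0.0444) or wild-type replicate 1 (0.0455), and the edgeR call for Runx2 ended without wild-type replicate 1 (adjusted p = 0.074) or 2 (0.052). Of 5 skeletal muscle markers, Actn3 (-2.01) was lower, also over the list alone (median -0.51, camera adjusted p = 0.204).

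Lists with fewer than 5 tested genes were not tested as sets, and their counts were the same adjusted over the list alone. Of 4 lymphocyte markers Igkc fell (log2 fold change -3.13, and -3.86 without knockout replicate 2), and of 3 mesothelial markers Krt8 fell (-3.43), where the list's median of 0.08 and mean of -0.91 differ in sign. Of 4 mammary epithelial markers Epcam (-5.62), Cdh1 (-3.44) and Krt7 (-1.72) fell and Esr1 (1.62) rose. Epcam, at 0.0677 ± 0.0737 CPM in knockout and 3.83 ± 0.839 in wild type, moved with the gut lining genes. With 1 library left out the log2 fold change of Epcam ran from -6.77 to -5.10 and that of Cdh1 from -4.16 to -2.97, both lowest without knockout replicate 3. No erythroid marker had enough counts to test. Of 5 sex-linked transcripts Eif2s3y rose (0.41) and Xist fell (-2.43) with 1 each over the list alone (median -0.05, camera adjusted p = 0.736). With Xist at 0.245 ± 0.169 and 1.36 ± 0.334 CPM and Eif2s3y at 86.2 ± 9.66 and 64.9 ± 2.34 CPM both genotypes had the transcripts of male cells. Of 33 neighbours of Ythdf1 on distal chromosome 2, 10 were higher and 6 lower, and adjusted over the list alone 11 and 6 (median 0.09, camera adjusted p = 0.635). Tcfl5 was at 0.970 ± 0.361 against 9.54 ± 2.12 CPM and Col20a1 at 17.0 ± 1.31 against 3.29 ± 0.337.

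Of the 34 lists tested, 22 passed camera with the preset correlation, 15 higher and 7 lower in knockout, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. With the rotation test fry, which asks whether the genes of a set move on balance in 1 direction and does not compare them with other genes, 24 passed.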

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

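The removal of the 50 most abundant genes and the GC and length offsets were chosen after the results had been seen, and the other alternatives were set before. Over the settings at the same threshold, without the replicates left out, 2989 to 3945 genes were higher and 2993 to 3879 lower, and 0 genes were called in opposite directions. Upper-quartile factors gave 44.8% of calls as higher, against 50.9% with TMM. Asking for a log2 fold change of at least 1 as well left 1326 higher and 991 lower by construction. With 1 replicate left out, 2741 to 3395 were higher and 2535 to 3279 lower, and the log2 fold change of Ythdf1 ran from -0.51 to -0.48. Replicate numbers gave no sign of pairing: deviations of same-numbered libraries correlated at -0.17, 0.02 and -0.16, and not every library correlated best with its own number. Differently numbered libraries correlated at -0.05 to 0.18. With 3 libraries per genotype these values depend on each other, so they cannot exclude pairing. The fit with the replicate block gave 3136 higher and 2993 lower and changed no list call, and the calls it ended among the genes named by rule were those of Prol1 (edgeR adjusted p = 0.108) and Tek (0.062). Of the 34 lists, 0 passed with an estimated correlation, against 22 with the preset one. Adjusted p-values with it were 0.19 for mature adipocyte markers, fatty acid and triglyceride synthesis, lipolysis, thermogenic genes, myofibroblast markers and TGF-beta signalling, 0.0824 for progenitor markers, 0.229 for the tricarboxylic acid cycle, 0.247 for matrix, 0.284 for Wnt signalling and 0.31 for adipogenic transcription factors. They were 0.335 for pericytes, 0.345 for oxidative phosphorylation, cholesterol, insulin signalling, cell cycle and NRF2 targets, 0.415 for glycolysis, 0.475 for mitochondrially encoded transcripts, 0.601 for ribosomal proteins and macrophages, and 0.609 for interferon genes. This setting allows for members that vary together. With fry, 24 lists passed: interferon genes (adjusted p = 0.0589), ribosomal proteins (0.0566) and macrophages (0.0754) no longer did, while m6A genes (0.0174), stress response (0.0464), skeletal muscle (0.0415), chondrogenic and osteogenic markers (0.00134) and neighbours of Ythdf1 (0.0111) did. Pericyte markers were lost with limma-voom (0.137) and skeletal muscle markers passed without the low-count filter (0.0498). With 1 replicate left out the camera adjusted p of chondrogenic and osteogenic markers ran from 0.0444 to 0.101. The cause of these changes was not tested. Of the genes named by rule, calls were lost in 1 or more settings for Tek, Prol1, Runx2, Cox4i2, Alkbh5 and Jun, with no change of sign. Not all losses came from leaving out a replicate. DESeq2 lost 2 of these calls, GC and length offsets 2, no low-count filter 3, the replicate block 2 and upper-quartile factors 1. Depth limits genes of low counts. Near 0.18 CPM lie 3 counts, and the filterByExpr minimum count of 10 sets a higher floor for a gene to be tested.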

Other observations

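The tests of a larger share of differentiated cells, of the share of the most abundant genes, of random gene sets beside the colon genes and of passenger variants near Ythdf1, and the fits without the 50 most abundant genes and with GC and length offsets, were chosen only after the result they bear on was seen, as were the patterns of gut genes and pseudogene copies themselves.

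Liver-made plasma protein genes were present at low levels in both genotypes, and 12 of 16 liver genes had all 3 wild-type libraries above the knockout libraries, with Alb at 27.7 ± 5.29 CPM against 12.1 ± 2.55 CPM in knockout, Fga at 5.92 ± 0.764 against 3.13 ± 0.524 and Mup3 at 4.16 ± 0.659 against 2.08 ± 0.396. In 2 liver genes every knockout library lay above the wild-type libraries: the enzyme gene Cyp2e1, which fat cells also express, at 3.67 ± 1.03 CPM in wild type and 35.6 ± 14.9 in knockout, and Trf, itself a plasma protein gene, at 2.22 ± 0.279 against 6.11 ± 1.31. Of 18 small intestine genes listed, 11 had at least 10 counts in total and were compared. In wild type 6 of these lay above every knockout library, among them Reg3b at 4.11 ± 1.09 CPM against 0.154 ± 0.147. Lyz1, also in the fixed list of macrophage markers, was at 0.154 ± 0.116 CPM in wild type against 1.85 ± 1.36, and Anpep at 63.6 ± 7.96 against 65.7 ± 5.55 CPM. Of 293 processed pseudogenes tested, 32 were higher and 14 lower in knockout, and 7 copies, Eno1b counted among them, were at least 8-fold higher while 0 were 8-fold lower.

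The first pattern is the rise of adipocyte genes with the fall of progenitor and collagen genes. The tables argue against trends in GC content and length and against a few abundant genes as its whole cause: the median log2 fold change of the mature adipocyte markers was 1.99 with the trends removed, against 2.12 as reported, and that of the progenitor markers was -0.82 against -0.78. The 50 most abundant genes took 18.5% to 22.1% of counts, which shifts every other gene by at most 0.0656 on the log2 scale between a knockout and a wild-type library. A larger share of differentiated cells in the knockout cultures, with no change within them, is a candidate explanation that cannot be told apart from a change within cells in bulk RNA: the matrix genes did not move by 1 factor (heterogeneity statistic of 57.7 per degree of freedom), but genes made by both kinds of cell would also move by less. The genotype, the difference the design names, stays among the open explanations as untested, since no test here tells an effect on differentiation apart from a different share of cells. A difference in handling that coincided with genotype was not tested and cannot be told apart from it.

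The second pattern is the presence of gut epithelial transcripts in the wild-type libraries. Of 34 colon genes listed before the test, 29 (85.3%) lay above every knockout library in all 3 wild-type libraries, so reads or cells of colon epithelium may have entered the wild-type cultures or libraries. Their ratios across those libraries varied more than counting noise alone (chi-square of 1.75 per degree of freedom) and lay barely under the 5th percentile of 1.78 of random sets of genes with like counts, and genes that the cultured cells make together would also keep a ratio, so a single shared source stays open. The most abundant genes of that list, Car4 at 33.5 ± 9.81 CPM in wild type and 42.4 ± 13.5 in knockout and Muc2 at 17.3 ± 0.822 against 13.8 ± 0.623, are also present in the knockout, Lgals4 had a higher mean there (8.54 ± 1.09 in wild type, 10.8 ± 1.92 in knockout), Krt36 was higher in every knockout library (3.20 ± 1.30 against 13.4 ± 1.63), and the rest reached at most 8.81 CPM in wild type. Of the genes listed for other organs, those with at least 10 counts in total were 16 of 16 from liver and 1 of 11 from kidney. They were 2 of 9 from lung, 1 of 12 from pancreas and stomach and 4 of 11 from skin. In wild type 13 of these 24 (54.2%) lay above every knockout library, 12 from liver, 1 from kidney and 0 of 7 from the others. All wild-type libraries lay below the knockout libraries for 2 liver genes, 1 pancreas and stomach gene and 1 skin gene. Outside liver too few genes had counts to decide, so RNA from several organs is also open. So are the route, with no sort named in the labels, and an untested genotype effect.

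The third pattern is the 7 copies at least 8-fold higher in knockout, of the parents Rplp0, Eno1, Me1 and Cyb5r4. A difference in alignment or trimming between the genotypes' libraries would shift copies as a set, and the median of copy minus parent log2 fold change over 252 copies was 0.0858. Reads of the parent counted on the copy were tested by whether the parent fell by what its copies gained: 4 of the 7 copies met this, 3 of them copies of Rplp0. Of the parents Rplp0 met it beyond its error (a change of -876 ± 80.5 CPM against a gain of 240 ± 29.0, SE). Ribosomal protein genes fell as a group (median log2 fold change -0.46), but Rplp0 fell further, by -1.41, against -0.79 for Rps18, the next largest fall. The group fall therefore does not account for all of the fall of Rplp0. That excess goes with reads moving to the copies but does not by itself show it. Me1 rose itself by 622 ± 75.8 against a gain of 12.7 ± 1.72. Because Me1 rose, this test cannot tell whether a share of its reads was counted on the copy. Eno1 changed by -25.3 ± 123 against a gain of 214 ± 14.9, and Cyb5r4 by -4.72 ± 2.73 against 4.36 ± 0.146. For these last parents the sum of parent and copies, 189 ± 124 and -0.359 ± 2.73, was within 2 standard errors of no change. A strain variant between the mice and the reference could move reads between a gene and its copy, and 7 of 253 copies on 5 chromosomes is the small number that needs, but genotype and any strain difference cannot be told apart without the reads. No other biological explanation was tested.

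Other tests gave the following values. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called 6561 genes in edgeR. The highest of the others called 0, with at most 353 genes at an unadjusted p under 0.05. Each of those others put both genotypes in each group, so the genotype difference widened the spread within groups. They therefore do not measure what chance would call, and 10 splits are too few for a share under 0.05. Processed pseudogene copies gained 2.25% of the summed CPM that ribosomal protein genes lost, their sum being 33470 ± 2889 CPM in wild type and 24060 ± 4215 in knockout. Within 5 Mb of Ythdf1, 37.3% of 59 genes were called, against a median of 44.1% and a 95th percentile of 55.9% in windows of as many genes elsewhere. The median log2 fold change of thermogenic genes exceeded that of mature adipocyte markers by 0.11 (2-sided permutation p = 0.717 across genes, which are not independent replicates).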
